A study of Solanum lycopersicum with 2 samples.

How the data were processed

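Total RNA of 35S::SlDREB2 tomato and of wild type, both under salt, was labelled through cDNA with Alexa Fluor 555 (green, channel 1) and Alexa Fluor 647 (red, channel 2), per the labels' protocols. The green channel held wild type on array 1 and the transgenic RNA on array 2. The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 9.1 per the submitters' processing notes, and a table of values for the series. Per the file headers, the scanner files hold spot and background intensities on a linear scale, processed signal intensities that are background-subtracted and dye-normalized, a log10 ratio of red over green with the software's own p-value per spot, and yes-or-no marks for spots above background, saturated or outlying. The authors' series table holds log10 ratios. Compared spot by spot with the scanner files, its values matched the deposited log10 ratio of red over green within 0.00496, without being turned for the dye swap, and the median of each column was 0. Both arrays lie on one slide, so slide could not be tested as a batch.

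Each array has 45220 spots, of which 1417 are controls. The other 43803 spots hold 43603 probes, and 50 of these are spotted 5 times. Outlier marks lay on 65 and 14 of the non-control spots of arrays 1 and 2, and no spot was saturated. Well above background were 46.6% and 57.2% of spots in green and 67.6% and 79.6% in red. The median SD of the 5 spots of a repeated measured probe was 0.03 on array 1 and 0.06 on array 2 (log2, 39 probes). The number of arrays limits the precision.

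Mean signals were corrected with the median local background by normexp with an offset of 50 in limma 3.58.1 (R 4.3.3). Ratios were normalized within each array by loess, with control and outlier spots at weight 0. Ratios were turned so that each is transgenic over wild type, spots of a probe were averaged and the arrays were averaged. Because of the offset, ratios of dim probes are pulled towards 0 and folds are understated. A probe was measured when it was well above background in at least 1 channel on each array and had no outlier mark, which kept 29324 probes. It was called by size when the mean log2 ratio was at least 1 in size, the sign was the same on both arrays and each array gave at least 1.5-fold. Where a genotype was not well above background on either array, its fold is a bound, computed per channel after loess and Aquantile scaling. The limma fit over the arrays, with Benjamini-Hochberg adjustment, was an alternative view.

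The rule for named genes was fixed before the data were examined. Among called probes whose annotation names a product, with the brightest probe per gene, it takes the 12 highest and the 12 lowest; it adds the target gene's probes and, for each list described, up to 4 called members, or the brightest members when fewer than 2 were called. Only 6 differently named genes were called higher. Of the members this takes, the text gives a selection. Gene names are those of the array design. Of 912 probes with a locus number as name, 380 were given a current symbol from the reference gene table (assembly SLM_r2.1), and of 2041 probes with a symbol 1759 matched a symbol or synonym there. A name was at hand for 3607 measured probes (12.3%), so lists hold only the named part of the array. The arrays' genome build is not given in the sources used here, and no coordinates are given.

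The 31 gene lists were word patterns matched to gene symbols and product names. Probes with one accession were averaged to a gene, which gave 21884 genes, 4620 of them with at least 2 probes (median SD between probes 0.05 log2); several accessions can belong to one gene. A list's median was set against 10000 random lists drawn in 10 bins of intensity. Numbers were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

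The steps were tested on simulated data. With 200 of 29285 probes changed in simulated spot signals, the size rule called 6% of 2-fold, 28% of 3-fold, 34% of 4-fold and 60% of 8-fold changes, with 0 calls among unchanged probes and 0 wrong signs, and limma called 12%, 38%, 52% and 74%. The median measured log2 ratio of a simulated 2-fold change was 0.36. The simulated dye effect was the same on both arrays and cancelled in the swap. No dye bias that changes with intensity and no difference between RNA pools was added. The 0 calls among unchanged probes therefore do not measure false calls on the real arrays. Of 100 random lists of 42 genes, 7 fell outside the central 95% with no shift and 95 did with a shift of 0.05.

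Alternatives were Agilent's processed signals, no background subtraction, median centring, Aquantile scaling, other filters on background, leaving out saturated spots, each array left out, the series table, other thresholds and, for limma, a trend. A normexp offset of 10 was added after the data had been seen. Control spots were left out of the comparisons.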

Results

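Gene expression was compared between tomato plants (Solanum lycopersicum, cultivar Ailsa Craig) that carry a 35S::SlDREB2 construct and wild-type plants. SlDREB2 is a transcription factor of the DREB family, whose members bind promoters of drought- and salt-responsive genes. Both genotypes were 6 weeks old, were grown in hydroponics and had been exposed to 125 mM NaCl for 48 h, so the comparison asks how the transcriptome of the overexpressor differed from wild type under salt. RNA came from 4 or more plants, of a tissue that the labels do not state. The RNA of the genotypes was hybridised together on 2 two-colour Agilent arrays, with the transgenic RNA in the red channel on array 1 and in the green channel on array 2. The sample labels call the arrays biological replicates, whereas the design text calls the dye swap a technical replicate. They were therefore counted as 1 replicate, so the difference between genotypes has no replicate check, no p-value between genotypes is given as the main result, and each SD below is that of the 2 arrays, which may cover only array and dye error. Median spot signals were low, at 69.0 and 72.0 units in green and 72.5 and 90.1 in red on arrays 1 and 2, over local backgrounds of 41 and 48. Of 43603 probes, 29324 were measured, that is, well above background in at least 1 channel on each array and free of outlier marks on both.

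The target gene came first as a check on the labels. The 2 probes that the array names DREB2 showed no higher level in the RNA labelled transgenic. Probe A_96_P211774, the brighter, had a log2 ratio of transgenic over wild type of 0.15 on array 1 and 0.01 on array 2 (mean 0.08 ± 0.10, SD of the arrays). Probe A_96_P013346 had -0.01 and -0.03 (mean -0.02 ± 0.01). The name DREB2 belongs to 2 genes in the reference gene table, and the array does not say whether its probes lie inside the transcribed part of the construct, so these probes may not check the labels at all. Directions below therefore refer to the RNA labelled transgenic, called transgenic for short.

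A probe was called changed when its mean log2 ratio was at least 1 in size, with the same sign on both arrays and at least 1.5-fold on each. By this rule 84 probes were higher and 61 lower in the transgenic RNA, 145 in all or 0.494% of those measured, and they belonged to 89 transcripts by accession. Only 33 of them carry the name of a gene or product, and 112 do not. The ratios of the arrays correlated across probes, with Pearson r = 0.72 and Spearman rho = 0.52 over all measured probes, although probes are not independent replicates. Over the brightest 25% of probes r was 0.80, and over the dimmest 25% 0.18. With median centring in place of loess, which leaves dye bias that changes with intensity, r turned to -0.42 over all measured probes and was 0.47 over the brightest 25%. The same rule applied to the dye contrast, in which the arrays' ratios have opposite signs, called 1 probe after loess and 1024 after median centring.

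**Figure D1:**
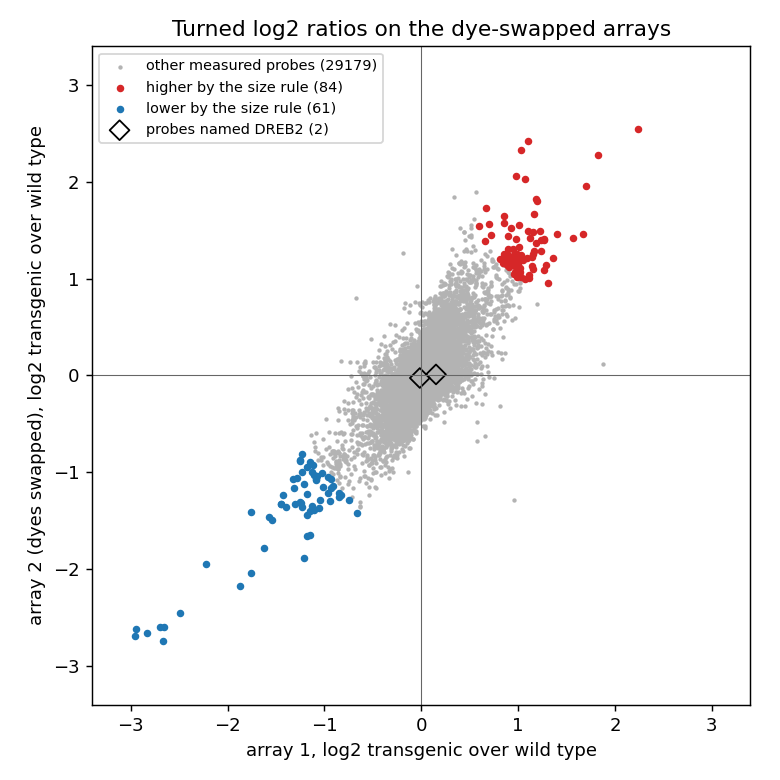
Log2 ratio of transgenic over wild type on array 1 (x axis) and on array 2, with the dyes swapped (y axis), 1 point per measured probe. The 84 higher probes (red) and 61 lower probes (blue) lie in opposite corners, and the 2 DREB2 probes (diamonds) lie near 0 on both axes.

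The named genes that were higher in the transgenic RNA come first. INS-1P, which encodes inositol-1-phosphate synthase, the first step of myo-inositol synthesis, was 2.96-fold higher (log2 1.57 ± 0.15), and its 3 probes ranged from 1.32 to 1.57. Fructose-bisphosphate aldolase, an enzyme of glycolysis and the Calvin cycle, was 2.09-fold higher (1.06 ± 0.06). The probe for bmy3 was higher at 1.19 ± 0.30 (0.98 on array 1), while the 4 probes of that transcript went from 0.42 to 1.19. A 101 kDa heat shock protein was 2.87-fold higher (1.52 ± 0.76), with 0.98 on array 1 and 2.06 on array 2, and its 4 probes ranged from 0.65 to 1.52. A heat shock cognate 70 kDa protein, a chaperone, was 2.19-fold higher (1.13 ± 0.61), but by 0.70 on array 1 alone. Neither passed in limma over the arrays (adjusted p = 0.0685 and 0.0833). CIP1, a CONSTANS interacting protein, was 2.41-fold higher (1.27 ± 0.21), and all 4 of its probes were called, between 1.08 and 1.27. With a second transcript of the 101 kDa heat shock protein (1.21 ± 0.51), these were all the named higher transcripts that met the rule.

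More named genes met the rule in the lower direction, and the 12 with the lowest ratios follow. The thiazole biosynthetic enzyme of the chloroplast, which makes the thiazole part of thiamine, was 6.26-fold lower (log2 -2.65 ± 0.07). A 24K germin-like protein was 3.25-fold lower (-1.70 ± 0.11). NRT2;1, a high-affinity nitrate transporter, was 2.93-fold lower (-1.55 ± 0.48), with -1.21 on array 1 and -1.89 on array 2. Its transgenic signal was not well above background on either array, so this fold was computed as a bound. Such a bound sets the mean of the bright genotype against the larger of the dim probe's own value and the lowest value among probes well above background. For NRT2;1 it equalled the plain mean ratio, and the ratio on array 1 was smaller in size. ER5, matched here by the list of LEA proteins, was 2.86-fold lower at one probe (-1.52 ± 0.08), while its other probe gave -0.43. LeGAD2, a glutamate decarboxylase that produces GABA, was 2.25-fold lower (-1.17 ± 0.16), with 3 of its 6 probes called and all of them below 0. GABA-TP2, a GABA transaminase that breaks GABA down, was 2.36-fold lower (-1.24 ± 0.11), with 1 of 4 probes called and the range from -1.24 to -0.70. GAD2 on this array is a different gene, a homolog of 2-oxoglutarate-dependent dioxygenases, and was 2.10-fold lower (-1.07 ± 0.26). Its call ended on array 2 alone (-0.89) and with no background subtraction (-0.996). DWARF1/DIMINUTO, an enzyme of sterol and brassinosteroid synthesis, was 2.11-fold lower (-1.08 ± 0.01). The cysteine proteinase cyp-3 was 2.36-fold lower (-1.24 ± 0.16), the wound-repressed transcript pT53 2.61-fold lower (-1.39 ± 0.09), the SGRP-1 protein 2.62-fold lower (-1.39 ± 0.08) and a 14-3-3-like protein, GF14 iota, 2.31-fold lower (-1.21 ± 0.22). With median centring 9 of the 18 named genes no longer met the rule, these being fructose-bisphosphate aldolase, LeGAD2, GABA-TP2, GAD2, DWARF1/DIMINUTO, cyp-3, pT53, SGRP-1 and GF14 iota. With Agilent's processed signals the fold grew by over 1.5 times for 6 of the 18. NRT2;1 moved furthest, to a log2 ratio of -6.06, so the size of its difference is not settled. The others were the 101 kDa heat shock protein (2.97), the heat shock cognate 70 kDa protein (2.93), ER5 (-2.96), GF14 iota (-2.59) and the 24K germin-like protein (-2.43). The order of genes by size therefore depends on the processing.

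**Figure D2:**
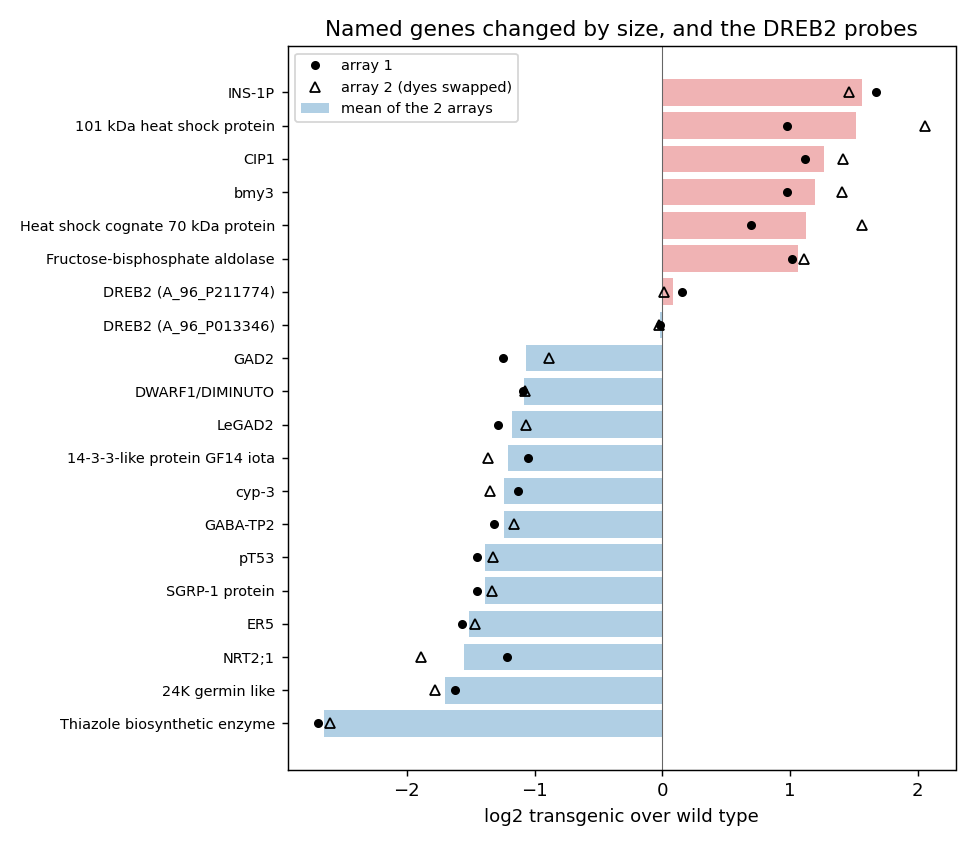
Log2 ratio of transgenic over wild type (x axis) for the 6 named higher genes, the 12 lowest named genes and the 2 DREB2 probes (y axis). Bars give the mean of the arrays, filled circles array 1 and open triangles array 2. The thiazole biosynthetic enzyme is lowest at -2.65 and INS-1P highest at 1.57.

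Large changes were also found at probes without a gene name. Their sequences were not aligned to any gene, so they may belong to genes named above. Probe A_96_P177709, with the sequence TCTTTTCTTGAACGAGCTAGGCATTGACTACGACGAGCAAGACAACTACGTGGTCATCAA, was 7.08-fold lower (-2.82 ± 0.19), and all 5 probes of its transcript were called, between -2.82 and -2.47. Probe A_96_P240398, with the sequence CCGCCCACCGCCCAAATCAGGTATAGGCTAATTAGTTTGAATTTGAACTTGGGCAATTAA, was 5.24-fold higher (2.39 ± 0.22). Probe A_96_P136097 was 4.15-fold higher (2.05 ± 0.31), and 7 of the 9 probes of its transcript were called.

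Gene lists fixed before the data were examined were then compared with 10000 random lists of the same size, matched on intensity, and list members were counted as changed by the rule above on the mean of a gene's probes. Of 27 lists with at least 3 measured genes, 2 had a median above and 9 below the central 95% of random lists. These percentiles describe the RNA hybridised here, not the genotypes in general, and most list medians were small. Cytosolic ribosomal proteins, a list set as a control, were among the 9 below. Random lists were drawn gene by gene and do not hold genes that vary together. A place outside their central 95% is therefore no sign of a response by itself.

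Heat shock proteins and chaperones, which fold proteins under stress, had a median log2 ratio of 0.14 over 42 genes (0.07 on array 1 and 0.20 on array 2), above all random lists (percentile 100), and 35 of the 42 lay above 0. The heat shock cognate 70 kDa protein (1.13 ± 0.61) and a second 101 kDa heat shock protein transcript (1.21 ± 0.51) were called higher, none was called lower and 40 were not called. The brightest members changed little, with -0.02 ± 0.06 for heat shock protein 70 and 0.13 ± 0.05 for heat shock protein 70-3. The lowest member was endoplasmic heat shock protein 90, at -0.37 ± 0.04. Aquaporins, the water channels of membranes, had a median of 0.17 over 9 genes (percentile 99.1) with no gene called, but 0.05 on array 1 and 0.34 on array 2. Among the brightest, major intrinsic protein 2-like had 0.64 ± 0.22 and PIP1-5 had 0.44 ± 0.01, while a tonoplast intrinsic protein had -0.73 ± 0.02.

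Of the lists below the central 95% of random lists, 6 follow. LEA proteins and dehydrins, which accumulate under water deficit, had a median of -0.19 over 4 genes (percentile 0.74) with none called. ER5 had a gene mean of -0.97 ± 0.13, LEA14 -0.27 ± 0.08 and TAS14, a salt- and abscisic acid-responsive dehydrin, 0.04 ± 0.21. The LEA median turned to 0.01 without the filter on background, and was -0.57 over genes well above background in both channels on both arrays, -0.31 with no background subtraction and -1.34 with Agilent's processed signals. Polyamine metabolism had a median of -0.28 over 6 genes (percentile 0.09; -0.13 on array 1 and -0.42 on array 2) with none called, and of its members an arginine decarboxylase 1, which starts putrescine synthesis, had -0.86 ± 0.04. Pathogenesis-related proteins had a median of -0.15 over 7 genes (percentile 0.14) with none called. That median was -0.003 without the filter on background, -0.32 over genes well above background in both channels on both arrays, and -0.36 with Agilent's processed signals. The protein NP24 precursor had -0.43 ± 0.08 and GluB -0.37 ± 0.16. The jasmonate and wound list had a median of -0.04 over 33 genes (percentile 0.11), and -0.016 on array 1. This list had -0.0014 over genes well above background in both channels on both arrays, and -0.28 with Agilent's processed signals. Its 1 called gene was pT53 (-1.38 ± 0.06), which is named as wound-repressed rather than wound-induced, and polyphenol oxidase D had -0.52 ± 0.03, lipoxygenase 0.10 ± 0.10 and a jasmonic acid-amino acid-conjugating enzyme 0.24 ± 0.02. Sodium, potassium and proton transport had a median of -0.05 over 15 genes (percentile 1.1) with none called, but the median was 0.01 on array 1 alone and also 0.01 with median centring in place of loess. Of its 4 brightest members, the proton ATPases LHA2 and LHA1 had -0.12 ± 0.04 and -0.14 ± 0.10, another plasma membrane H+-ATPase 0.01 ± 0.12 and the potassium channel LKT1 0.08 ± 0.09. Cell wall loosening and remodelling had a median of -0.07 over 77 genes (percentile 0) with none called, and -0.04 on array 1 and -0.08 on array 2. The brightest of its transcripts named cellulose synthase had -0.25 ± 0.26. The list's median was -0.01 without the filter on background, -0.02 with median centring and -0.27 with Agilent's processed signals.

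The list of DREB, CBF and ERF factors lay inside the central 95% of random lists. It had a median of 0.01 over 15 genes (percentile 67.5), with none called and a median of -0.0075 on array 2 alone. Among the brightest, values ran from -0.26 ± 0.08 for JERF1 to 0.22 ± 0.21 for ethylene response factor 3. Most members are named ERF, JERF or PTI, so the median says little about the transgene's own DREB family. Members named DREB or CBF were DREB2 (gene mean 0.03 ± 0.05), DREB3 (0.003 ± 0.07) and CBF3 (-0.02 ± 0.06). The offset pulls ratios of dim members towards 0, so these flat values do not exclude a change. The lists for abscisic acid, gibberellin, ethylene and auxin were also inside the central 95% of random lists and had no called gene. Abscisic acid had a median of -0.03 (5 genes, percentile 26.5; NCED1, the enzyme that commits carotenoids to abscisic acid synthesis, had -0.18 ± 0.11), gibberellin 0.09 (5 genes, just inside the upper limit; 0.02 on array 1 and 0.15 on array 2), ethylene -0.01 (19 genes, percentile 19.4) and auxin 0.01 (25 genes, percentile 64.8). So were sugar and polyol metabolism, at 0.02 (27 genes, percentile 87.3), where another inositol phosphate synthase transcript had 0.57 ± 0.20 and which does not hold INS-1P, bmy3 or the called aldolase, antioxidant and glutathione enzymes at -0.02 (32 genes, percentile 8.01), where APX1 had -0.56 ± 0.07 and ER60 0.81 ± 0.11, and phenylpropanoid and flavonoid synthesis at 0.02 (17 genes, percentile 70.7). Of the transcription factor lists, WRKY had 0.06 (9 genes, percentile 93.6; 0.03 on array 1 and 0.0016 on array 2), NAC -0.03 (6 genes, percentile 12.04) and MYB 0.02 (10 genes, percentile 87.9), with none called. The circadian list had -0.03 (8 genes, percentile 18.9), and its 1 called gene was CIP1, which entered it by the word CONSTANS. On a single array the median of 15 of the 16 lists inside the central 95% moved by over 1.5 times or crossed 0. For cytokinin and proline metabolism 2 genes each were measured, too few for a percentile.

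**Figure D3:**
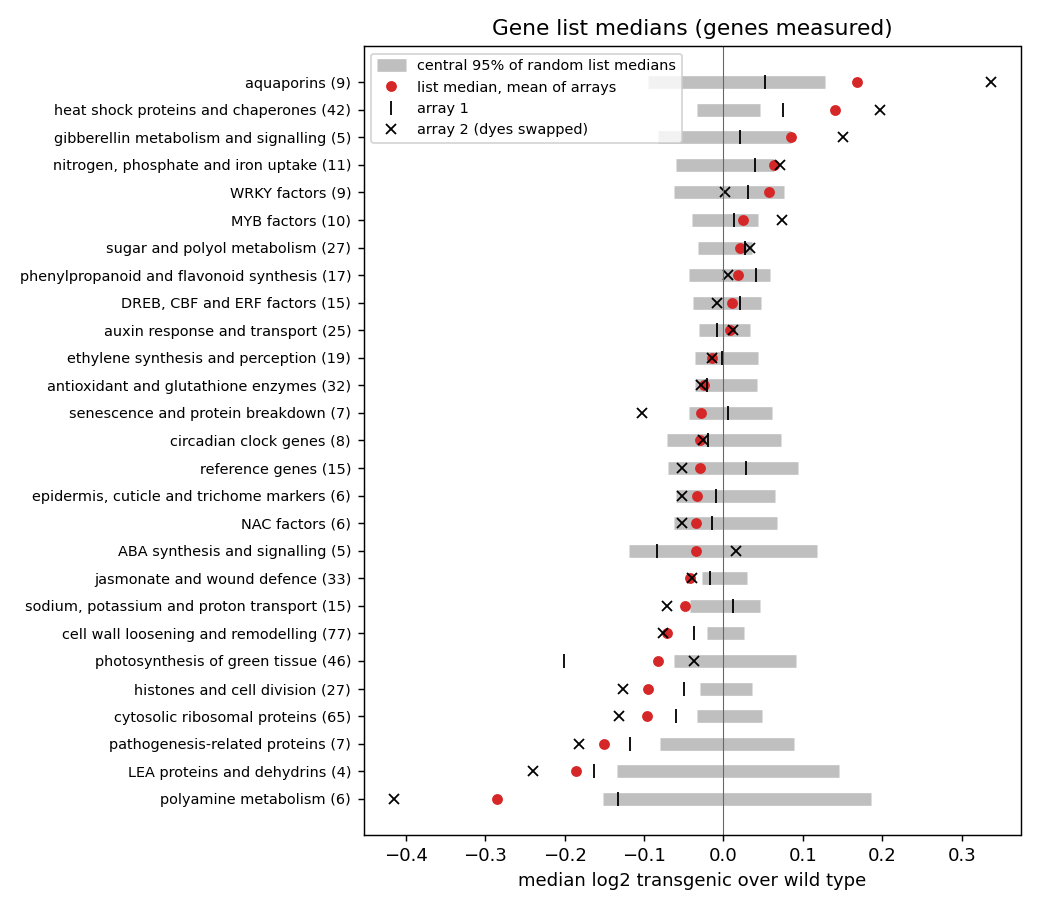
Median log2 ratio of transgenic over wild type (x axis) of each gene list with at least 3 measured genes (y axis, number of genes in brackets). Red points give the mean of the arrays, bars and crosses the single arrays, and grey bands the central 95% of 10000 random lists. Heat shock proteins and chaperones (0.14) and aquaporins (0.17) lie above their bands and 9 lists lie below.

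Read as biological replicates, the arrays gave 416 higher and 347 lower probes in limma at an adjusted p of 0.05 (763 in all, 134 of them among the 145), with 1 residual degree of freedom per probe. In that fit 2 of 64 heat shock and chaperone probes passed over all probes and 18 adjusted over the list alone, 16 of these higher; for aquaporins 6 of 14 passed over all probes and 7 adjusted over the list alone. For pathogenesis-related proteins 2 of 20 probes passed over all probes and 15 adjusted over the list alone, all lower, and for polyamine metabolism 1 and 3 of 10. Lists inside the central 95% of random lists also held such probes. For sugar and polyol metabolism 5 of 52 passed over all probes and 17 adjusted over the list alone, 16 of these higher; for senescence and protein breakdown 6 and 11 of 15, all lower; and for antioxidant and glutathione enzymes 6 and 11 of 42, of which 1 was higher. For photosynthesis of green tissue, a list below the central 95%, the numbers were 6 and 22 of 77, all lower. If the swap was technical, these p-values measure only array and dye error. Probes of one gene were counted separately, so these are not counts of independent genes. The 20 pathogenesis-related probes belonged to 7 genes, and the 15 senescence probes also to 7.

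The number of called probes depended on the processing. Agilent's processed signals gave 1241 higher and 843 lower probes, along with 582 in the dye contrast, and median centring in place of loess gave 60 higher and 14 lower, a higher share of 81.1% against 57.9%. By the same size rule on single arrays, array 2 alone gave 173 higher and 88 lower and array 1 alone 49 and 62.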

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

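The tests on the patterns below were chosen after the results had been seen, except the count of higher probes at or below the intensity of the brighter DREB2 probe.

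Spike-in control spots named E1A, which no comparison uses, gave a signal above that of the negative control spots. Of 320 such spots, 47.8% in green and 84.1% in red were well above background on array 1, and 53.1% and 90.0% on array 2. Of 153 negative control spots, 1.31% in green and 1.96% in red were well above background on array 1 and 0 on array 2.

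The DREB2 probes were flat in the RNA labelled transgenic (mean log2 0.08 and -0.02). Against 1 array being labelled with its dyes the wrong way round, the turned ratios correlated at r = 0.801 over the brightest 25% of probes (0.47 with median centring, where r over all measured probes was -0.42). Dimness of the brighter probe as the cover of a 2-fold rise is argued against by its log2 ratio of 0.138 ± 0.14 with Agilent's processed signals, to which no normexp offset was added, and that probe was brighter than 83.9% of measured probes. For the dimmer probe dimness stays open, and the count of probes at or below the brighter one's intensity, 4 called higher and 7 lower, did not decide it. It also stays open whether the probes do not read the construct's transcript (2 genes carry the name in the reference table).

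The heat shock and chaperone list lay higher. Dye bias would turn its sign between the dye orientations, and the lower of the medians on the single arrays was 0.0749. A few strongly changed members would leave the rest around 0, whereas 83.3% of the list's genes lay above 0. The list was singled out for its high median, however, so a large share above 0 was nearly given in advance. Several accessions can also belong to one gene. The share shows that the shift was spread over many entries, but it is no independent support. The median without the 2 called genes was 0.13, but leaving out 2 of 42 genes can hardly move a median, so this value decides nothing. A difference between these RNA pools unrelated to the transgene cannot be told apart from an effect of SlDREB2, because there was 1 pool per genotype as the arrays were counted here. An effect of the transgene under salt stays open as a hypothesis.

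Agilent's processed signals gave more called probes (2084 against 145). The gained probes had a median log2 intensity of 6.74, close to the 6.82 of all measured probes. The 145 were brighter than most, at 8.73. Noise of dim probes as the whole cause is argued against by the dye contrast, which gave 27.9% as many calls as the genotype contrast. Compression of dim probes' ratios by the normexp offset is consistent with the 268 probes called with an offset of 10. How much each adds stays open, and no biological explanation was tested.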

How the results depend on the processing

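The offset of 10 was chosen after seeing the data. Leaving out saturated spots and Aquantile scaling could not change a ratio, since no spot was saturated and that scaling leaves ratios as they are. Low signal over background limits the dim probes most. No paired analysis was possible because the arrays form a single group, so that no replicate number is shared between groups; the ratio within an array, which all results use, already sets the genotypes side by side. Unless a reason is given, the cause was not tested. The 145 called probes (84 higher, 61 lower) became 2084 (1241, 843) with Agilent's processed signals, 2082 (1239, 843) with the series table, 239 (145, 94) with no background subtraction, 268 (158, 110) with an offset of 10, 74 (60, 14) with median centring, 16 (5, 11) with a 3-fold threshold, which is stricter by construction, and 763 (416, 347) with limma. With each array left out the total ran from 111 to 261, the higher probes from 49 to 173 and the lower from 62 to 88. All 145 were called without the background filter, with the scanner's p-values added and with an offset of 10. The limma count of 763 became 184 without the background filter, 0 with Agilent's processed signals (5132 at an unadjusted p under 0.05, against 4804) and 1883 with a trend. The correlation of the arrays over all measured probes, 0.72, became 0.46 with Agilent's processed signals and with the series table. Over the brightest 25% of probes, however, r was 0.85 with Agilent's processed signals against 0.80. With median centring the correlation over all measured probes turned to -0.42, and the dye contrast called 1024 probes. The mean over the DREB2 probes, 0.03, became -0.0347 with Agilent's processed signals, -0.035 with the series table and 0.0919 with median centring. The number of lists outside the central 95% of random lists, 11, stayed within 1.5 times in all 13 alternatives. Of 324 recomputed list medians, 130 moved by at least the SD of the arrays, not counting 5 of lists outside the central 95% that turned in sign. With Agilent's processed signals 23 of the 27 medians lay over 1.5 times further from 0 on the same side, such as heat shock proteins at 0.35, abscisic acid at -0.30 and MYB factors at 0.31. In all 23 of the 324 lay on the other side of 0, in 12 lists. Of these, 18 belonged to lists inside the central 95% of random lists, such as senescence, ethylene, auxin and reference genes, and 5 to lists outside it: with median centring, transport to 0.0087, photosynthesis to 0.0491 and ribosomal proteins to 0.0063; without the background filter, LEA proteins to 0.0057; and transport ran from -0.0711 without array 1 to 0.0115 without array 2. Over the 5 settings that can move a named gene's ratio freely, none of 90 mean ratios changed sign, and 51 moved by at least the SD of the arrays. The kept signs say little, because these genes were chosen for large ratios of the same sign on both arrays. In addition, the processed signals and the series table hold nearly the same values. On array 1 with median centring, pT53 (0.0033), DWARF1/DIMINUTO (0.0938) and GAD2 (0.0855) did turn above 0. With Agilent's processed signals 6 of the 18 folds grew by over 1.5 times and 0 shrank by as much. With median centring 9 of the 18 named genes were no longer called.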

Other observations

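A control list and lists for tissue make-up also differed from random lists. Cytosolic ribosomal proteins, set as a control, had a median log2 ratio of -0.10 over 65 genes (percentile 0), with 5 genes above 0 and none called. The median was -0.06 on array 1 and -0.13 on array 2. With median centring in place of loess it turned to 0.0063, but its percentile was still low at 0.04. Among the brightest members, 40S ribosomal protein S25 had -0.31 ± 0.16 and 60S ribosomal protein L10 -0.13 ± 0.05. Histones and cell division genes had -0.09 over 27 genes (percentile 0; -0.05 on array 1 and -0.13 on array 2), with 4 above 0 and none called, and the brightest histone H2B transcripts had -0.31 ± 0.12 and -0.30 ± 0.13. Photosynthesis genes of green tissue had -0.08 over 46 genes (percentile 0.6), with -0.20 on array 1 and -0.04 on array 2, none called, and a turn to 0.0491 with median centring. Its brightest members are plastid-encoded, and photosystem Q(B) protein had 0.58 on array 1 and -0.48 on array 2. All these measured genes come from RNA of a tissue the labels do not state.

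Of the remaining lists, 4 lay inside the central 95% of random lists. Nitrogen, phosphate and iron uptake had a median of 0.06 over 11 genes (percentile 97.4), and its 1 called gene, NRT2;1, went the other way, 2.93-fold lower. Senescence and protein breakdown had -0.03 over 7 genes (percentile 8.99), with cyp-3 called lower (-1.02 ± 0.19 over its 3 probes) and the proteinase cp at -0.76 ± 0.15. That median was -0.76 over genes well above background in both channels on both arrays and -0.37 with each probe counted by itself, but 0.04 with Agilent's processed signals. Epidermis, cuticle and trichome markers had -0.03 over 6 genes (percentile 11.4). Reference genes had -0.03 over 15 genes (percentile 15.5), and the beta-tubulin TUB was called lower (-1.07 ± 0.23), while elongation factor 1-alpha had -0.24 ± 0.12. Phloem and xylem markers had 2 measured genes each, too few for a percentile, with SUT2 at -0.08 ± 0.09 and a xylem cellulose synthase at 0.01 ± 0.15.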
